A study of Mus musculus with 6 samples.

How the data were processed

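RNA from placentas of Swiss Webster mice was measured on 6 2-colour arrays (3 of female and 3 of male placentas), each holding 1 pool of APA and 1 pool of control placentas of 1 sex. Per the labels, sires were 15 months (APA) or 3 months (control) old, dams 3 months, with 3 breeding pairs per group, and a pool held 1 to 3 placentas with at most 1 per sex from each dam. The 6 pools of an age group came from 3 breeding pairs, so some must share a sire and dam. Which dams the pools came from is not given in the sources used here, nor is the day of gestation. Per the labels APA RNA carried Cy3 and control RNA Cy5 on every array, so no dye swap exists. Per the file headers, the arrays lay on 3 slides, which coincide with 3 scans: slide 1 held female replicate 1, slide 2 female replicates 2 and 3, and slide 3 all male arrays.

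The deposited scanner files hold, per the file headers, spot and local background intensities without normalization, and processed intensities that Agilent Feature Extraction 10.10.1.1 had background-subtracted, spatially detrended and dye-normalized. They also hold log10 ratios of the processed Cy5 over Cy3 signal, per the file headers, and 0 or 1 flags for spots well above background, saturated or non-uniform, as deposited. A further table by the authors holds log2 ratios of APA over control, normalized and centred near 0. How the authors normalized it is not given in the sources used here. Its direction was read from the values, and its columns correlated at 0.947 to 0.991 with the log2 ratios computed here over probes above background.

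Mean spot signals were corrected with normexp (offset 50) and each array was normalized by loess in limma 3.58.1 (R 4.3.3, with the data.table package, version 1.17.8), with control spots given no weight and then left out. Each array held 44397 spots, of which 43020 were probe spots for 39429 probes, and the other 1377 were control spots. Spots of a probe were averaged. A probe was tested when well above background in at least 3 of 12 array channels (26552 probes), and each gene was represented by its tested probe with the highest mean signal, which gave 20372 genes, 15280 of them with a gene symbol and 4935 with at least 2 tested probes. Probes were named through a table of RefSeq accessions and symbols, 28025 by accession, 3413 by symbol and 295 by a unique synonym, while 4985 kept the name in the file and 2711 had only a probe name. Probe positions are those of the files (mm9). Sequence matches of the probes to other genes were not examined, so members of the Psg, Ceacam, cathepsin and prolactin families can share signal.

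Log2 ratios of APA over control were fitted in limma with a mean for each sex over all 6 arrays, so that both sexes shared 1 estimate of the spread (4 residual and 2.5 prior degrees of freedom). The contrasts were the female mean, the male mean, their average and female minus male. Male and female pools were compared within each dye on log2 channel values after Aquantile normalization between arrays. Benjamini-Hochberg adjusted p below 0.05 over all genes was the threshold. All adjusted p-values are from limma. Lists of genes were tested with limma's camera (preset correlation 0.01) in the female, male and female minus male contrasts, adjusted over the 27 lists, beside camera with an estimated correlation and fry. Of 29 lists of textbook genes, the Y-linked and X inactivation lists served only the check of sex labels. The lists are those of trophoblast giant cell and placental hormone, spongiotrophoblast and junctional zone, glycogen trophoblast, labyrinth syncytiotrophoblast, endothelial, decidual stromal and maternal uterine, erythroid, yolk sac and visceral endoderm, uterine natural killer and lymphoid, macrophage and neutrophil, and paternally and maternally expressed imprinted genes. The others cover DNA methylation and chromatin regulators, nutrient transporters, the insulin-like growth factor axis, hypoxia and glycolysis, inflammatory and cytokine, interferon response, oxidative stress and glutathione, unfolded protein response and heat shock, cell cycle, oxidative phosphorylation, ribosomal protein, immediate early, steroid hormone and cholesterol synthesis, extracellular matrix and autism risk genes.

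Genes were named by a rule. For each sex it took the 12 largest rises and the 12 largest falls among called genes with 1 sign on all 3 arrays, filled up by smallest p where fewer were called, and 6 of each for the other comparisons. From each list it took the 4 members of smallest p, of which the text prints a part. Clone, accession and predicted names were counted and not named. Tpbpa, Tpbpb, Prl8a8, Sfrp4, Pgr, Gzmc and Gzmf lay outside this rule and were chosen after their values were seen. The groups, comparisons, tests, thresholds, lists, naming rule and most alternatives were chosen before the data were examined.

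Alternatives changed 1 choice at a time, except that the processed signals replaced background correction and normalization together and the authors' table replaced all steps up to the log2 ratios. They were the processed signals of the image software, no background subtraction, no filter or a filter on all 12 channels, the mean of all probes of a gene, trended and robust moderation, array weights, the replicate number or the slide as a block, median centring of each array on all its spots in place of loess, a separate channel fit, the authors' log2 table, the arrays of 1 sex alone, quantile normalization of single channels, and leaving out each array in turn. Chosen after the data were seen were removal of the trend of log ratios with brightness (a running median over 151 genes), centring on the median of the tested genes, and, for the lists, centring on all spots, no background subtraction and the authors' table. With 1 array of a sex left out, the 2 others of that sex were assumed to vary like the other sex.

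The procedure was tested on simulated data of 20372 genes with 200 changed genes. Each gene had its residual spread from these arrays, drawn alike and independently for all 6 arrays. At log2 sizes of 1, 2 and 4 it recovered 79.1%, 94.0% and 98.5% of them in females, 83.6%, 95.5% and 100% in males, 89.6%, 97.0% and 100% over both sexes, and 67.2%, 95.5% and 97.0% for female minus male. In the control and APA sex comparisons it recovered 65.7% and 80.6% at log2 1. False calls numbered 8 to 16 among 181 to 202 calls. The real arrays differed in noise, with a median SD between replicate spots of 0.0355 to 0.0376 on female and 0.103 to 0.142 on male arrays. Some of their pools must also share a breeding pair, so these rates need not hold for them. Genes called in the arrays had a smaller median absolute log2 ratio, 0.492 in males and 0.295 over both sexes. Recovery at such sizes was not tested. A shift of 0.5 log2 in each of 27 lists in turn was recovered for 27 lists, and for 26 with an estimated correlation, with 1 call of another list. Most lists called in the arrays shifted by less than 0.5. The simulated genes were independent, so this does not speak to false calls among correlated genes, and in the arrays the estimated correlation reached 0.784 (erythroid genes). Probes well above background per array made up 56.5%, 60.6% and 58.3% in female APA, 58.8%, 59.6% and 53.8% in male APA, 60.3%, 65.6% and 63.7% in female control and 67.9%, 68.7% and 68.6% in male control pools. Spike-in and negative control spots were left out of the comparisons, and no array was left out. Spots flagged non-uniform in either channel were left out on that array, and a probe without a spot left on any array was not tested. Probes were otherwise left out for their values only by the background filter above and the choice of 1 probe per gene.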

Results

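RNA was measured in mouse placentas sired by old males (15 months, here APA) or young males (3 months, here control), all carried by 3-month-old dams of 3 breeding pairs per paternal age group. Each of 6 2-colour arrays set an APA pool of placentas (Cy3) against a control pool of the same fetal sex (Cy5), with 3 arrays for female and 3 for male placentas, so 12 pools were measured. The day of gestation is not given in the labels. Of the probes, 53.8% to 60.6% in APA and 60.3% to 68.7% in control pools lay well above background, and no spot was saturated. Replicate spots of a probe differed in log2 ratio by a median SD of 0.0355 to 0.0376 on female arrays and 0.103 to 0.142 on male arrays. After filtering, 20372 genes were tested. APA had the same dye on every array, so a dye effect of a probe adds in full to each comparison of APA with control. It cancels between the sexes only where it is equal on female and male arrays, and genes brighter than log2 16 had median ratios of -0.29 to -0.26 on female and -0.07 to -0.03 on male arrays.

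The sex of the pools was checked first. Ddx3y, a Y-linked RNA helicase, lay at log2 9.47 to 10.28 in the 6 male pools and at background (5.82 to 6.16) in the 6 female pools. Eif2s3y, a Y-linked translation factor, lay at 8.13 to 9.28 in male pools against 5.83 to 6.17. Xist, the RNA that silences 1 X chromosome in female cells, lay at 9.93 to 10.34 in female pools and at 7.53 to 7.91 in 5 male pools, with 6.44 in the control pool of male replicate 2. All 12 pools carried the expression of their labelled sex, and the male pools also held Xist well above background.

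The first question was which genes differed with paternal age in female placentas. Adamdec1, a member of the ADAM metalloprotease family (probe on chromosome 14, 69181473 to 69181532, mm9), rose 110-fold, from a mean log2 signal of 7.47 in control to 14.25 in APA pools (log2 6.78, SD 0.42, n = 3, SE 0.18, higher on 3 of 3 arrays, adjusted p = 1.31e-04). Its second probe gave log2 3.02. Klk4, a kallikrein-related serine protease (chromosome 7, 51141115 to 51141174), rose 2.58-fold (log2 1.37, SD 0.16, n = 3, 3 of 3 arrays, adjusted p = 0.0443). These 2 were the genes past the adjusted 0.05 level in limma, with 3879 genes below an unadjusted 0.05.

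The next genes by p, n = 3, had the same sign on 3 of 3 female arrays and did not pass (adjusted p = 0.0874). On the higher side stood Gdpd3 at log2 1.75 (SD 0.54), Pnp2, a purine nucleoside phosphorylase, at 2.30-fold (SD 0.24), the co-chaperone Bag3 at log2 1.05 (SD 0.15) and the kallikrein Klk7 at 0.85 (SD 0.16). Smaller ratios were those of Eif5a at 0.57, Tmem138 at 0.48, the Hsp70/Hsp90 co-chaperone Stip1 at 0.48, Ube2s at 0.45, Olfr1466 at 0.41 and the apoptosis gene Bax at 0.39. On the lower side stood Zfp874a at log2 -1.17 (SD 0.30), Rpl23 at -0.69 (SD 0.05, with 1 of its 2 other probes of the same sign) and Rps14 at -0.56 (SD 0.01). Close to these were Noxo1 at -0.56, Ecrg4 at -0.55, Cpne5 at -0.54, Rpl10 at -0.53, Rack1 at -0.53, Rps10 at -0.52 and Elp5 at -0.49. Rpl23, Rps14 and Rpl10 belong to the list of ribosomal protein genes, whose median brightness was log2 16.3. Genes brighter than 16 had medians of -0.262, -0.286 and -0.289 on the female arrays, and this trend was not removed from the ratios given here. Ceacam15 was at least 1.42-fold lower. Such a bound is given where the signal of 1 group was well above background on none of its arrays, and it is as open to dye bias as a ratio. Actg1 was at -0.80 (adjusted p = 0.0824), but of its 4 other probes only 1 had the same sign (-0.65 to 0.20).

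In limma Adamdec1 passed in 21 of 21 alternatives in females (log2 4.90 to 7.13, adjusted p 2.94e-08 to 0.0341) and Klk4 in 10 of 21 (adjusted p 0.00126 to 0.47). The count of 2 became 1 without female replicate 2 or 3 or male replicate 1 or 3, and 1359 without male replicate 2. Male arrays do not enter the female mean, so they change this count only through the estimate of the spread that both sexes share. With female arrays fitted alone the count was 11. The count of 2 thus depends on the spread of the male arrays too. Both called genes were higher ones, against 14% of the calls with arrays centred on the median of all spots and 61.1% with centring on the median of the tested genes.

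In male placentas 263 genes passed, 37 higher and 226 lower (190 with a gene symbol). Adamdec1 rose 56.4-fold (log2 5.82, SD 0.31, n = 3, SE 0.18, 3 of 3 arrays, adjusted p = 3.55e-04), and its second probe gave 2.81. The other named genes lay close to the threshold (adjusted p 0.0468 to 0.0472), each with its sign on 3 of 3 arrays. The largest rises were in Rem1, a small GTPase (2.59-fold, SD 0.54 on the log2 scale, chromosome 2, 152460868 to 152460927), Ica1l (2.27-fold, SD 0.44), Pnp2 (2.12-fold, SD 0.22, chromosome 14, 51584365 to 51584424), Bag3 (2.10-fold, SD 0.21, chromosome 7, 135690281 to 135690340) and Klk4 (1.99-fold, SD 0.21). Also higher were Mc3r, a melanocortin receptor (1.78-fold, SD 0.22), Olfr1466 (1.68-fold, SD 0.05), Spinkl (1.62-fold, SD 0.17), Gpr157 (1.61-fold, SD 0.13), Myh6, a cardiac myosin heavy chain (1.60-fold, SD 0.12), and Klk7 (1.55-fold, SD 0.16). Adamdec1 passed in 20 of 21 alternatives (adjusted p 1.57e-07 to 0.0658). Bag3, Mc3r, Olfr1466 and Gpr157 lay below 0 where each array was centred on the median of all spots in place of loess (log2 -0.03, -0.21, -0.35 and -0.44). This scaling moved the median of all genes by -0.37 in females, -0.69 in males, -0.54 over both sexes and 0.25 for female minus male.

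Genes that fell in males included the carboxypeptidase-like Cpxm1 (log2 -0.85, SD 0.24), Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1 (-0.77, SD 0.21), the adhesion molecule Ncam1 (-0.75, SD 0.14, chromosome 9, 49310320 to 49310379) and the keratin Krt25 (-0.73, SD 0.19). Falls of similar size were those of Mtcl1 (-0.72, SD 0.18), Tmem37 (-0.71, SD 0.12), Dennd4a (-0.67, SD 0.11, with 2 of its 4 other probes of the same sign), the uracil-DNA glycosylase Ung (-0.67, SD 0.14), the collagen gene Col1a1 (-0.66, SD 0.20) and the kinase Pak4 (-0.62, SD 0.12). Zfp874a fell at least 1.70-fold (fit adjusted p = 0.047). The thyroid hormone transporter Slc16a2 fell at least 1.44-fold (fit adjusted p = 0.0468), but lay at 0.65 when each array was centred on the median of the tested genes. In limma 4759 genes lay below an unadjusted 0.05 in males. The count of 263 became 2 without female replicate 1, 3 without male replicate 2 and 1 without any other array, and 1 when only male arrays were fitted. Called genes were 14.1% higher ones, against 56.4% when arrays were centred on the median of the tested genes.

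Female and male log2 ratios were compared next. Across all genes they correlated at r = 0.662 (rho = 0.544) and shared their sign in 67.8%, and 246 of the 263 genes called in males had the same sign in females. The 2 genes called in females were among the 37 that rose in males, against 0.00363 by chance with independent calls. The calls were not independent, since both sexes shared 1 estimate of the spread and some pools of an age group must share a breeding pair. Since the dye layout is shared, these figures do not separate paternal age from dye.

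**Figure D1:**
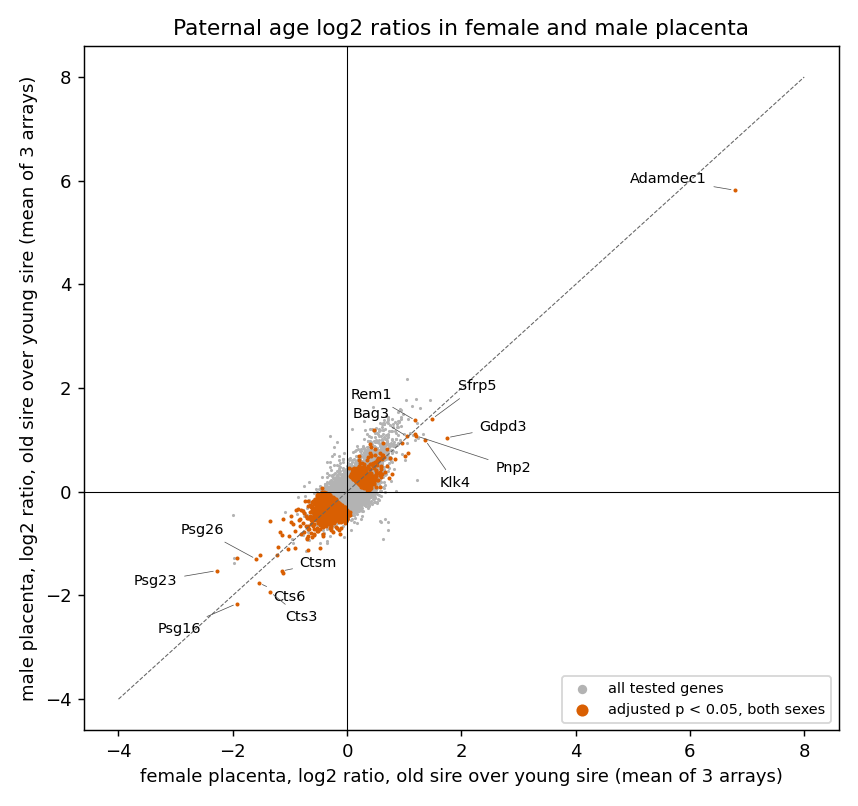
Mean log2 ratio of APA over control in female (n = 3 arrays) and male (n = 3 arrays) placenta for 20372 genes. Orange marks the 1819 genes past the adjusted 0.05 level over both sexes, and the dashed line marks equal ratios.

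Over both sexes 1819 genes passed, 432 higher and 1387 lower, and all named ones had their sign on 6 of 6 arrays. Adamdec1 rose most (log2 6.30, SD 0.62, n = 6, adjusted p = 2.25e-05). It was followed by Sfrp5, a secreted Wnt inhibitor (2.73-fold, SD 0.92, adjusted p = 0.0472), Gdpd3 (2.63-fold, SD 0.59, adjusted p = 0.0174), Rem1 (2.44-fold, SD 0.37, adjusted p = 0.0172), Klk4 (2.27-fold, SD 0.26, adjusted p = 0.0126) and Klk15 (2.21-fold, SD 0.72, adjusted p = 0.0467). The largest falls were in genes of placental trophoblast families. Among pregnancy-specific glycoproteins, which the placenta secretes, Psg16 fell to log2 -2.04 (SD 0.79, adjusted p = 0.02, chromosome 7, 17683714 to 17683774), Psg23 to -1.90 (SD 1.12, adjusted p = 0.0346) and Psg26 to -1.44 (SD 0.75, adjusted p = 0.0308). Among placental cathepsins, Cts6 fell to -1.65 (SD 0.79, adjusted p = 0.0269), Cts3 to -1.64 (SD 0.73, adjusted p = 0.0211, chromosome 13, 61666111 to 61666170) and Ctsm to -1.34 (SD 0.63, adjusted p = 0.025).

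Sequence matches of probes among members of the Psg, cathepsin and prolactin families were not examined, and the 2 other probes of Psg16 gave only -0.32 and -0.22. In limma 6247 genes lay below an unadjusted 0.05 over both sexes. The count of 1819 became 8 without female replicate 1, 1980 without male replicate 2 and 1 without any of the other 4 arrays. Adamdec1 passed in 20 of 20 alternatives (adjusted p 1.48e-09 to 0.0106). Higher genes made up 23.7% of the calls, against 52.7% when arrays were centred on the median of the tested genes.

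Gene groups were then compared in female placentas with camera over 27 lists, of which 10 passed with the preset correlation and 0 with an estimated one (2 lists below an unadjusted 0.05). With the signs of some female arrays reversed, up to 11 lists passed with the preset correlation, so the count of 10 does not stand out. A second tool, fry, which asks whether a list moves one way on balance and not against other genes, called 1 list. The trophoblast giant cell and placental hormone genes fell (22 genes, mean log2 -0.58, SD 0.30 over 3 arrays, lower on 3 of 3, adjusted p = 2.57e-05), and adjusted p = 0.772 with an estimated correlation. In that list 0 genes passed over all genes and 10 fell when adjusted over the list alone. Its members included the placental lactogen Prl3b1 at -1.23, the proliferin gene Prl2c5 at -0.99 and the cathepsin Ctsj at -0.91. The spongiotrophoblast and junctional zone genes fell (30 genes, mean -0.46, SD 0.37, means of -0.03, -0.60 and -0.74 on the 3 arrays, adjusted p = 7.42e-05), and adjusted p = 0.822 with an estimated correlation. Here 6 genes fell over the list alone and 0 over all genes, and Tpbpa and Tpbpb, markers of this layer, lay at -0.63 and -0.70, Psg23 at -2.28 and Ceacam13 at -1.20. Both lists had means below 0 under every scaling tried. The 2 median centrings say little here, since they also lowered another bright list. Unfolded protein response and heat shock genes (median brightness log2 13.4) lay at -0.61 and -0.25 with them, and the hormone and junctional zone lists had 13.9 and 13.1. Decidual stromal and maternal uterine genes had a mean of 0.24 (adjusted p = 0.248). Uterine natural killer and lymphoid genes rose in the test (21 genes, mean 0.18, SD 0.31, means of -0.03, 0.03 and 0.53, adjusted p = 0.0499), but had a mean of -0.24 with arrays centred on the median of all spots, and adjusted p = 0.883 with an estimated correlation. Its member of smallest p, the granzyme Gzma, lay the other way at -1.98 (SD 1.03, adjusted p = 0.255).

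Ribosomal protein genes also fell in females (46 genes, mean -0.19, SD 0.03, lower on 3 of 3 arrays, adjusted p = 9.93e-08), with adjusted p = 0.27 with an estimated correlation and 0.0019 by fry. Over the list alone 24 fell and 3 rose. Their median brightness was log2 16.3, and genes brighter than 16 had medians of -0.26, -0.29 and -0.29 on the 3 female arrays. With that brightness trend removed the list lay at -0.02 (adjusted p = 0.498), and with the processed signals at -0.05 (adjusted p = 0.459, over alternatives 7.65e-22 to 0.498). Erythroid genes fell (27 genes, mean -0.32, SD 0.45, means of -0.51, -0.65 and 0.19, adjusted p = 0.00131), and adjusted p = 0.866 with an estimated correlation. Over that list alone 6 fell, the adult alpha globins Hba-a1 and Hba-a2 lay at -1.12 and -1.34. Without female replicate 3 the mean was -0.58, and without female replicate 2 it was -0.16 and the call was lost (adjusted p = 0.201, over alternatives 1.09e-11 to 0.866). Nutrient transporters fell (38 genes, mean -0.10, lower on 3 of 3 arrays, adjusted p = 0.0149, Slc1a1 at -0.44), and adjusted p = 0.479 with an estimated correlation, and without female replicate 3 adjusted p = 0.0719.

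Steroid hormone and cholesterol synthesis genes rose in females (32 genes, mean 0.14, SD 0.15, higher on 3 of 3 arrays, adjusted p = 0.00713), with Srebf2, a regulator of cholesterol synthesis, at 0.35 and Sqle at 0.32, and adjusted p = 0.772 with an estimated correlation. Without female replicate 3 the mean was 0.06 (adjusted p = 0.0719), and with either median centring the test turned to lower, at means of -0.35 on all spots and 0.02 on the tested genes. Hypoxia and glycolysis genes (36 genes, mean 0.13, 3 of 3 arrays), interferon response genes (38 genes, mean 0.10, 3 of 3 arrays) and cell cycle genes (40 genes, mean 0.07, 2 of 3 arrays) rose at adjusted p = 0.0499 each, and adjusted p = 0.866, 0.866 and 0.883 with an estimated correlation. With either median centring the test of these 3 lists turned to lower (means of -0.49, -0.35 and -0.40 on all spots and of -0.13, 0.01 and -0.04 on the tested genes). These calls were also lost without some arrays. For hypoxia these were female replicate 1 (adjusted p = 0.108), female replicate 3 (0.123) or male replicate 3 (0.0515), and for interferon female replicate 2 (0.208) or 3 (0.0719) or male replicate 3 (0.0515). For cell cycle they were female replicate 2 (0.966) or male replicate 1 (0.0518) or 3 (0.0515), and for natural killer genes female replicate 3 (0.386) or male replicate 3 (0.0515). Over the lists alone, 3 hypoxia genes rose and 2 fell, and the glycolysis gene Pfkl lay at 0.59 but Gapdh at -0.37. Against their lists also lay the interferon gene Ifih1 at -0.38 and the cell cycle gene Gmnn at -0.27. The count of 10 lists became 5 without female replicate 3 and 6 without male replicate 3.

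The other lists did not pass in females. Their means were, for glycogen trophoblast genes -0.10 (adjusted p = 0.562), labyrinth syncytiotrophoblast genes -0.09 (0.263), endothelial genes -0.02 (0.836) and yolk sac and visceral endoderm genes 0.04 (0.709). They were, for macrophage and neutrophil genes 0.06 (0.414), paternally expressed imprinted genes -0.13 (0.0821), DNA methylation and chromatin regulators -0.06 (0.303), and inflammatory and cytokine genes 0.04 with a median of -0.01 (0.562). The rest were oxidative stress and glutathione genes -0.01 (0.836), unfolded protein response and heat shock genes 0.07 (0.233), oxidative phosphorylation genes -0.02 (0.934), immediate early genes 0.15 (0.112), extracellular matrix genes -0.03 (0.263) and autism risk genes -0.03 (0.934). Maternally expressed imprinted genes had a mean of 0.02, a median of -0.03 and a test towards lower (0.562), with the imprinted RNA H19 at -0.61. The insulin-like growth factor axis had a mean of 0.01 and a test towards lower (0.709).

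In male placentas 7 of 27 lists passed camera with the preset correlation, 0 with an estimated one (0 lists below an unadjusted 0.05) and 1 by fry. With the signs of some male arrays reversed, 14, 9 and 16 lists passed with the preset correlation, more than on the real arrays. Spongiotrophoblast and junctional zone genes fell most (30 genes, mean log2 -0.67, SD 0.33 over 3 arrays, lower on 3 of 3, adjusted p = 2.04e-08), and adjusted p = 0.859 with an estimated correlation. In this list 1 gene fell over all genes (Ncam1) and 19 over the list alone, among them Tpbpa at -0.80, Tpbpb at -0.91, the metalloprotease Pappa2 at -0.81, Psg21 at -1.09 and the prolactin family gene Prl8a8 at -1.56. Trophoblast giant cell and placental hormone genes fell (22 genes, mean -0.60, SD 0.33, lower on 3 of 3, adjusted p = 3.21e-04), and adjusted p = 0.859 with an estimated correlation, with 10 fallen and 1 risen over the list alone, Cts3 at -1.94, Ctsm at -1.53 and Prl3b1 at -1.22. Both lists had means below 0 under every scaling tried and without each array, though the hormone list missed the threshold with arrays centred on the median of all spots (-1.65, adjusted p = 0.053). The 2 median centrings say little on these bright lists. They also put oxidative phosphorylation genes, of similar brightness (log2 13.6), at -1.10 on all spots and -0.41 on the tested genes. Paternally expressed imprinted genes fell (36 genes, mean -0.19, SD 0.09, lower on 3 of 3, adjusted p = 0.0335), and adjusted p = 0.859 with an estimated correlation, with 7 fallen over the list alone and Dlk1, a growth regulator, at -0.86. That call was lost without male replicate 2 or 3 (adjusted p = 0.118 and 0.171).

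**Figure D2:**
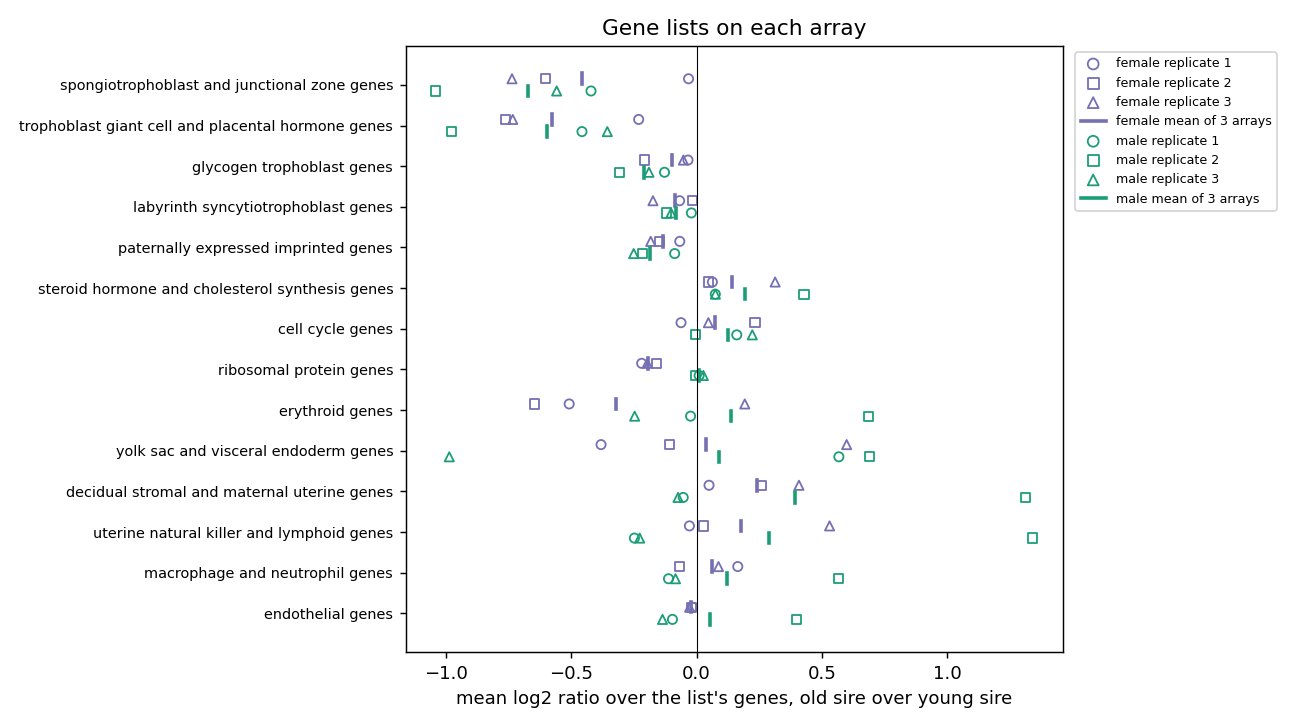
Mean log2 ratio of APA over control over the genes of 14 lists on each of the 6 arrays, with the mean of the 3 arrays of a sex as a bar. Decidual and natural killer genes lay at 1.31 and 1.34 on male replicate 2, against 0.53 or less on each other array.

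Decidual, natural killer, macrophage and endothelial genes moved on 1 male array beside these falls. Decidual stromal genes had array means of -0.05, 1.31 and -0.07 (mean 0.40, adjusted p = 0.152), uterine natural killer genes -0.25, 1.34 and -0.23 (mean 0.29, adjusted p = 0.0305), macrophage and neutrophil genes -0.11, 0.57 and -0.08 (mean 0.12, adjusted p = 0.559) and endothelial genes -0.10, 0.40 and -0.14 (mean 0.06, adjusted p = 0.559). The natural killer list rose with the preset correlation, with adjusted p = 0.859 with an estimated correlation, and without male replicate 2 its mean turned to -0.24 (adjusted p = 0.409, over alternatives 0.00116 to 0.859), and with arrays centred on the median of all spots to -0.34. Members with large mean ratios were the decidual genes Sfrp4 at 1.80 and Pgr, the progesterone receptor, at 1.36, and the granzymes Gzmf at 1.04 and Gzmc at 0.97, while of the natural killer list Gzma lay at -1.37 and Itga2 at -0.38. The interferon response genes rose (38 genes, mean 0.19, means of -0.05, 0.53 and 0.08, adjusted p = 0.00659), and adjusted p = 0.859 with an estimated correlation, and without male replicate 2 they lay at 0.01 (adjusted p = 0.387). Their member of smallest p, Stat1, lay the other way at -0.25 (adjusted p = 0.0742). With either median centring the test of the interferon list turned to lower (means of -0.57 on all spots and 0.12 on the tested genes).

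**Figure D3:**
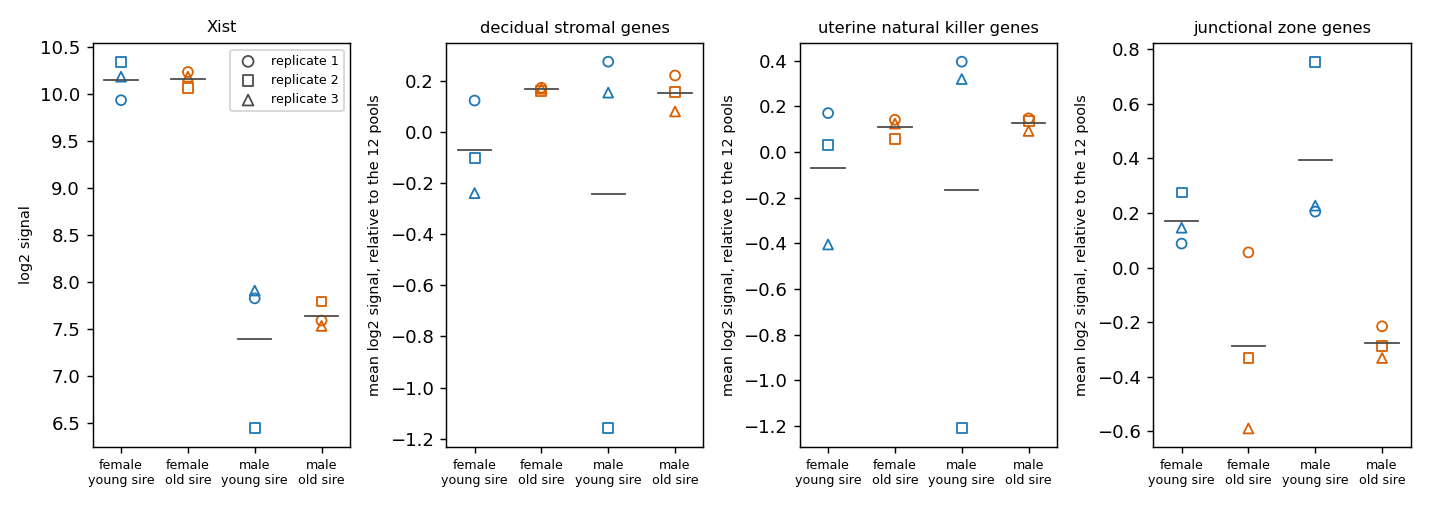
Log2 signal of Xist and mean log2 signal of 3 gene lists, relative to the 12 pools, in each pool of placentas. The control pool of male replicate 2 had Xist at 6.44 and a decidual level of -1.16.

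Cell cycle genes rose in males (40 genes, mean 0.13, SD 0.12, higher on 2 of 3 arrays, adjusted p = 0.00189), and adjusted p = 0.859 with an estimated correlation, with 4 risen over the list alone, the replication clamp Pcna at 0.45 and the licensing factor Cdt1 at 0.36. Without male replicate 3 the call was lost (mean 0.08, adjusted p = 0.118), and without male replicate 2 the mean was 0.19. Steroid hormone and cholesterol synthesis genes rose (32 genes, mean 0.19, SD 0.20, 3 of 3 arrays, adjusted p = 0.00567), and adjusted p = 0.859 with an estimated correlation, with 6 risen and 1 fallen over the list alone, Idi1 at 0.72 and Hsd17b2 at -0.61. The steroid list had array means of 0.07, 0.43 and 0.07, and without male replicate 2 its mean was 0.07 (adjusted p = 0.0166). With either median centring the test of both lists turned to lower, at means of -0.68 and -0.67 on all spots and 0.01 and 0.01 on the tested genes. Autism risk genes, short of the camera threshold (mean -0.08, adjusted p = 0.537), fell by fry (35 genes, lower on 3 of 3 arrays, adjusted p = 0.0151), with the synaptic gene Nrxn2 at -0.43. With arrays centred on the median of the tested genes the list lay at 0.06 and Nrxn2 at 0.35.

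The other lists did not pass in males. Their means were, for glycogen trophoblast genes -0.21 (adjusted p = 0.113), labyrinth syncytiotrophoblast genes -0.08 (0.559), yolk sac and visceral endoderm genes 0.09 (0.659, array means of 0.57, 0.69 and -0.99), DNA methylation and chromatin regulators -0.05 (0.559), and nutrient transporters -0.01 (0.459). They were, for hypoxia and glycolysis genes 0.05 (0.559), inflammatory and cytokine genes 0.11 (0.113), oxidative phosphorylation genes 0.01 (0.559), ribosomal protein genes 0.01 (0.552) and immediate early genes 0.15 (0.489). Mean and median differed in sign for erythroid genes (0.14 and -0.01, adjusted p = 0.598), oxidative stress and glutathione genes (0.06 and -0.01, 0.713), unfolded protein response and heat shock genes (0.05 and -0.03, 0.559), the insulin-like growth factor axis (0.01 and -0.05, 0.768, test towards lower) and extracellular matrix genes (0.03 and -0.05, 0.768, test towards lower). For maternally expressed imprinted genes the mean was 0.13, the median 0.01 and the test towards lower (0.973). Single members that fell over all genes were the erythroid gene Hemgn (-0.51), the collagen Col3a1 (-0.59), the imprinted signalling gene Gnas (-0.44, with 1 of 2 other probes of the same sign), the methyltransferase Suv39h2 (-0.48, with its other probe at 0.07), the transporter Slc1a1 (-0.38) and the granulocyte receptor Csf3r (-0.47), at adjusted p 0.047 to 0.0478.

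Whether the sexes differed in the paternal age effect was tested as female minus male. Ribosomal protein genes were lower in the female effect (46 genes, mean -0.20, female means of -0.22, -0.16 and -0.20 against male means of 0.01, -0.01 and 0.03, adjusted p = 1.14e-13, and 0.00671 by fry), with adjusted p = 0.0969 with an estimated correlation. With the brightness trend removed, which can take out a part of the list's own shift, the list lay at -0.06 (adjusted p = 0.143, over alternatives 2.45e-14 to 0.16). It lay at -0.06 with the processed signals and -0.12 with the mean of all probes, and with arrays centred on the median of all spots its mean turned to 0.09. Members with large differences were Rps20 at -0.52 (second probe -0.45), Rplp0 at -0.46 and Rps14 at -0.42, and 17 were lower over the list alone. Erythroid genes were lower (27 genes, mean -0.46, female means of -0.51, -0.65 and 0.19 against male means of -0.02, 0.68 and -0.25, adjusted p = 8.07e-05), with Hba-a2 at -0.78, and adjusted p = 0.979 with an estimated correlation. Junctional zone genes were higher (30 genes, mean 0.22, adjusted p = 0.0393), with Psg28 at 0.82, and adjusted p = 0.979 with an estimated correlation. Without female replicate 2 the erythroid call was lost (mean -0.30, adjusted p = 0.0872), and the mean was -0.19 without male replicate 2 and -0.72 without female replicate 3. Without female replicate 1 or male replicate 2 the junctional zone call was lost (mean 0.00 and 0.03, adjusted p = 0.997 and 0.815), and the mean was 0.35 without female replicate 3 and 0.34 without male replicate 1. The count of 3 lists by camera was 0 with an estimated correlation (1 list below an unadjusted 0.05) and 1 by fry, and became 5 without male replicate 1 and 8 without male replicate 2. Each array slide held 1 sex, so these differences cannot be told from differences between slides.

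Of single genes 0 passed for female minus male in limma (smallest adjusted p = 0.463), with 1898 below an unadjusted 0.05, while limma with array weights called 2700 and with slide as a random block 1008. The largest differences by p, none past the threshold, were the higher Aadacl4fm1 (0.65), Rnf32 (0.64), Tmem138 (0.60), Zfp157 (0.52), Ccl1, a chemokine (0.49), and Nrbp1 (0.47), and the lower Spinkl (-0.83), Rps20 (-0.52), the phosphatase Dusp26 (-0.50), Tceal7 (-0.49, with its other probe at 0.30), Fau (-0.43) and Rps14 (-0.42). Rps20 and Rps14 belong to the ribosomal protein list, whose difference shrank with the brightness trend removed.

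Male and female pools were last compared within each dye. In control pools Ddx3y rose at least 12.3-fold in males (fit log2 3.96, SE 0.14, adjusted p = 7.93e-04, higher in 3 of 3 pools, chromosome Y, 598215 to 598274), the one gene called, with 3088 below an unadjusted 0.05. Short of the threshold (adjusted p = 0.185) stood Eif2s3y, at least 5.46-fold higher, Ndufaf5 at log2 1.08, Wdr89 at 0.83, the metallothionein Mt3 at 0.73, Zfyve1 at 0.57 and Uty, at least 1.24-fold higher. Wdr89 had its other probe at -0.01. On the lower side stood Xist at -2.76, the potassium channel Kcnj13 at -1.02, the integrin Itgb4 at -0.84, the tight junction gene Cldn6 at -0.80, the DNA methyltransferase Dnmt3b at -0.75 and Ccdc85c at -0.58.

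In APA pools 5900 genes passed, 2844 higher and 3056 lower in males. Ddx3y rose at least 9.73-fold, Eif2s3y at least 6.21-fold and Uty at least 1.21-fold (fit adjusted p = 5.69e-06, 4.57e-06 and 0.0068), and Xist fell to log2 -2.52 (SE 0.10, adjusted p = 6.75e-06, chromosome X, 100656289 to 100656348). Ica1l rose 2.58-fold (adjusted p = 0.0107), the embryonic globin Hbb-bh1 2.53-fold (0.0173), Ndufaf5 2.05-fold (0.00614) and Arl14epl 1.94-fold (0.00911). Gcm1, the transcription factor of labyrinth syncytiotrophoblast, fell to -1.71 (SE 0.21, adjusted p = 0.00644), with its 3 other probes at -1.49 to -0.51. Other genes that fell in males were Spp2 at -1.70 (0.0144), the fibrinogen chain Fgb at -1.58 (0.0108), Ambp at -1.52 (0.0107) and albumin, Alb, at -1.44 (0.0275). All 3 male arrays shared 1 slide and the female arrays 2 others, so sex and slide are confounded here. The count of 5900 became 1914 without female replicate 2, 2942 without female replicate 3, 3661 without male replicate 2, 3597 without male replicate 3 and 3 with the processed signals of the image software, all 3 higher in males against 48.2% of the 5900. In control pools the count of 1 became 3 without male replicate 2. A difference between the 2 sex comparisons was tested only as the female minus male effect above.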

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

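Of the tests weighed here, those on the brightest spots, on maternal tissue in all APA pools and on maternal tissue in the control or the APA pool of male replicate 2 were chosen only after the result was seen, as were removal of the brightness trend and centring on the tested genes. A test of whether male replicate 2 alone carried the second pattern was written and then dropped to keep to 3 explanations, and its values are given there.

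A difference between the sexes in the paternal age effect drew attention to 3 lists. The mean log2 difference, female minus male, was 0.215 for spongiotrophoblast and junctional zone genes, -0.459 for erythroid genes and -0.203 for ribosomal protein genes, the last being -0.06 with the brightness trend removed. A signal in data outside the comparisons was that of the spike-in controls, whose Cy5 signal lay 12.1, 22.8 and 13.7 times over the negative control spots on the female arrays and 507, 355 and 294 times on the male arrays. Their Cy3 signal was 15, 9.17 and 10.9 times their Cy5 signal on female and 0.66, 0.802 and 0.759 times on male arrays. The spike-in amounts are not given in the sources used here, and the cause was not tested.

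The first pattern weighed is that log2 ratios were shared by female and male arrays (r = 0.662), with Adamdec1 at 6.78 and 5.82. A dye bias of single probes was tested on the 4927 genes with a second tested probe, where the mean ratios of the brightest and second probe correlated at r = 0.563, past the bound of 0.5 set against it as the whole cause, but the rank correlation was 0.401, r in males alone 0.462 and 63.4% of pairs had 1 sign, and over the 433 called genes with a second probe the median was log2 0.0928 there against 0.304 at the brightest, with 73.9% of 1 sign. Base composition of the probe explained 2.69% of the variance, between the bounds set for and against it, and decides nothing. Of the 32 ways to reverse arrays, the real one called 1819 genes over both sexes and the highest other 0, 1 of 32 with as many. This would exclude chance only if the 6 arrays were independent. The 6 pools of an age group came from 3 breeding pairs, so some must share a sire and dam, and chance is not excluded. Reversing arrays also takes a dye effect out of the mean, so this does not part age from dye. A dye bias of single probes stays open for a part of the genes, and a dye effect shared by a gene's probes, a DNA difference between the sires and paternal age stay open as untested.

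The second pattern is that hormone and junctional zone genes were lower in APA pools. With the brightness trend removed, the medians of both lists together were -0.408 in females and -0.535 in males, against -0.427 and -0.561 before. The hormone and junctional zone lists had a median brightness of log2 13.9 and 13.1. Over all genes, those of log2 12 to 14 and 14 to 16 had medians of -0.0119 to 0.0387 on the arrays. Removing the trend could thus move the list medians little, and this test does not decide on a bias of the brightest spots. Of the second probes of list genes, 90.9% (10 of 11) lay below 0, which argues against a bias of single probes for those genes. The 2 lists together held 52 genes, so most were not covered. Probes that share signal within a gene family would also weaken this test. More maternal tissue in all APA pools would raise decidual and natural killer genes on every array. The bound also used macrophage and endothelial genes, which can be of fetal origin, and left out erythroid genes, so it did not test blood. The 4 medians all lay at or below 0 on 2 arrays (male replicates 1 and 3), where the hormone and junctional zone lists together had means of -0.436 and -0.473. The decidual medians there were -0.0146 and -0.0222 and those of natural killer genes -0.156 and -0.0919. This argues against more maternal tissue as the cause on those 2 arrays. On the other 4 the means of both lists were -0.116, -0.672 and -0.735 (female replicates 1 to 3) and -1.01 (male replicate 2) beside decidual medians of -0.0103, 0.196, 0.342 and 0.988, so the fall was largest where decidual genes were highest, and there a part played by maternal tissue stays open. A smaller share of junctional zone in the APA pools through dissection, a dye effect shared by a gene's probes, and paternal age stay open as untested, and with an estimated correlation the lists had adjusted p = 0.772 and 0.822 in females and 0.859 for both in males.

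The third pattern is that among male arrays maternal tissue genes were higher in APA on replicate 2 alone (decidual median 0.988), with female replicate 3 next of all 6 arrays at 0.342. Its replicate spots had an SD 3.78 times the median of the other 5 arrays, which met the bound set for poor quality, but male replicate 1 had 3.70 without the pattern, a comparison added after the SDs were seen, so the test does not decide. More maternal tissue in the APA pool is argued against, since its decidual median lay -0.13 from the higher of the other APA male pools. Less maternal tissue in the control pool may be a source, since Xist lay -1.38 from the lower of the other control male pools. The decidual median lay -1.13 from it, which follows from the ratio where the APA pool is not higher. Eif2s3y, a gene of the male fetus, also lay 1 log2 lower and Ddx3y 0.458 higher. On this array erythroid (mean 0.684), extracellular matrix (0.514) and immediate early genes (0.522) were higher too. Cell cycle and ribosomal protein genes lay at -0.00477 and -0.00586, and hormone and junctional zone genes at -0.976 and -1.04. The difference was thus not limited to lists of maternal tissue. Other differences of that control pool stay open, and no biological explanation was tested.

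Other splits of the arrays were counted for each comparison. With 4 splits for a sex and 10 for the other comparisons, they are too few for a share below 0.05. In females the real arrays gave 2 genes and the highest other split 0 (1 of 4 with as many), and 10 lists against 11 (2 of 4). In males they gave 263 genes against 0 (1 of 4) and 7 lists against 16 (4 of 4). For female minus male they gave 0 genes against 0 (10 of 10) and 3 lists against 14 (10 of 10). In males and for female minus male every other split called more lists than the real one. List counts with the preset correlation of 0.01 thus do not set the real arrays apart. Estimated correlations reached 0.784 (erythroid genes), and with them 0 lists passed on the real arrays. Whether the preset correlation or a structure of the samples gave the counts of the other splits was not tested. Between the sexes they gave 1 gene against 0 in control (1 of 10) and 5900 against 0 in APA pools (1 of 10).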

How the results depend on the processing

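Removal of the brightness trend, centring on the tested genes, and for the lists centring on all spots, no background subtraction and the authors' table were tests chosen only after the data were seen, and a change of sign was taken as a reversal only where the value in the report or the alternative passed its threshold, a choice also made after seeing the values. Over 411 values of named genes, 6757 of 8345 comparisons with an alternative kept their direction and side of the threshold, 472 fell short of it, 1068 newly passed it and 48 reversed. Over 81 list values, 1200 of 1377 kept both, 96 fell short, 48 newly passed and 33 reversed. Adamdec1 passed in 21 of 21 alternatives in females (log2 4.90 to 7.13), 20 of 21 in males (4.31 to 6.17) and 20 of 20 over both sexes (4.61 to 6.65). The results rest on 3 arrays per sex and a single dye layout. The cause of each change below was not tested unless it is named.

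Counts of called genes were 2 in females, 263 in males, 1819 over both sexes, 0 for female minus male, 1 between the sexes in control and 5900 in APA pools. With Agilent processed signals they were 1, 70, 744, 0, 2 and 3. With no background subtraction the first 3 were 1, 2051 and 2962, and with no filter on dim probes males had 615 and both sexes 2865. With only probes well above background in all 12 channels they were 1, 1 and 1169, and 0 between the sexes in control (2581 below an unadjusted 0.05, and 0 to 2449 genes under the other limma alternatives), where Ddx3y, at background in female pools, was by construction not tested. With the mean of all tested probes males had 152, and with trend and robust moderation the first 3 were 1, 1 and 1134, of which 1 was higher and 1133 lower, against 432 and 1387 of the 1819. Array weights gave 3681, 8362, 7995, 2700 and 2 for the first 5. Slide as a random block gave 2415, 11062, 9160, 1008, 2449 and 9521, with slide correlations of -0.382 for the ratios and -0.333 and -0.211 for the control and APA channels, and such negative correlations shrink the errors by construction. The separate channel fit gave 726, 1582, 3354, 0 and 618, the series matrix values 1 in females and 1358 in males, and arrays of this sex alone 11 and 1. With the brightness trend removed males had 1 and both sexes 1136, of which 33.0% were higher.

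Without each array in turn, counts ranged from 1 to 1359 in females (the most without male replicate 2), 1 to 3 in males, 1 to 1980 over both sexes, 1 to 3 between the sexes in control and 1914 to 4991 in APA pools, and stayed at 0 for female minus male. A test without 1 array has fewer residual degrees of freedom. Arrays of the other sex change the female or male count only through the shared estimate of the spread. Without female replicate 1, which leaves the females on 1 slide, they were 3 in females, 2 in males and 8 over both sexes.

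The replicate numbers were not taken to pair the samples. Deviations of arrays with the same number correlated at 0.274, -0.388 and -0.55. Arrays of different numbers correlated at -0.338 to 0.547. The highest were female replicate 3 with male replicate 2 (0.547) and female replicate 2 with male replicate 3 (0.485). Whether such arrays shared a dam or a batch was not tested. Deviations from a mean of 3 arrays sum to 0, so each array has correlations of both signs with the other sex. These values are thus weak ground for or against pairing. The replicate block, which takes up degrees of freedom, gave 1 gene in females, 0 in males (3259 below an unadjusted 0.05 in limma), 1 over both sexes and 0 between the sexes in control.

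Median centring in place of loess, on all spots, moved the median of all genes to -0.37 in females and -0.69 in males and called 11766, 15727 and 16422 genes in females, males and both sexes. Median centring on the tested genes called 8009, 12222 and 13316. Genes that reversed with centring on all spots were, in females, Pygl -0.47, Tpi1 -0.44, Isg15 -0.38, Bst2 -0.41, Gpx4 -0.61, Mki67 -0.40, Ube2c -0.41, Mcm6 -0.50, Cox6b1 -0.41, Sqle -0.34, and in males Bag3 -0.0264, Mc3r -0.21, Olfr1466 -0.35, Gpr157 -0.44, Ugp2 -0.83, Cd3e -0.70, Zbp1 -0.30, Usp18 -0.63, Hsph1 -0.59, Asns -0.86, Pcna -0.63, Cdt1 -0.72, Birc5 -0.74, Mcm6 -0.75, Cox7c -0.88, Rpl7a -0.93, Rpl19 -0.95, Klf2 -0.46, Dhcr24 -0.83, Hmgcs1 -0.75, Scn2a 0.28. With centring on the tested genes they were, in females, Gjb6 0.34, Slc1a3 0.30, Gpx4 -0.25, and in males Slc16a2 0.65, Prl5a1 0.51, Clec14a 0.24, Itga2 0.57, Usp29 0.58, Inpp5f 0.61, Car9 0.30, Stat1 0.80, Gsta4 0.41, Rpl7a -0.24, Rpl19 -0.27, Nrxn2 0.35, Scn2a 0.96. With no background subtraction Mx1 reversed in males (-0.64).

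Lists called were 10 in females, 7 in males and 3 for female minus male. They were 0, 0 and 0 with an estimated correlation (2, 0 and 1 below an unadjusted 0.05) and 1, 1 and 1 with fry. With Agilent processed signals 5 were called for female minus male, and with only probes above background in all 12 channels 6 in females. With the brightness trend removed 5 were called in females, and with the series matrix values 6. Median centring in place of loess called 5 for female minus male, and median centring on the tested genes 12 in males and 8 for female minus male. Without each array in turn they ranged from 5 to 13 in females, 5 to 10 in males and 2 to 8 for female minus male. Without female replicate 1 the test of junctional zone genes for female minus male turned to lower, while their mean stayed above 0 (0.00277). Means that reversed without an array were those for female minus male of decidual genes (0.303, and -0.391 at the lowest, without male replicate 3) and natural killer genes (0.414) without male replicate 2, and that of natural killer genes in males without male replicate 2 (-0.238, and 0.558 at the highest, without male replicate 1).

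Lists whose test reversed with centring on all spots were, in females, hypoxia and glycolysis genes -0.49, interferon response genes -0.35, unfolded protein response and heat shock genes -0.61, cell cycle genes -0.40, steroid hormone and cholesterol synthesis genes -0.34, in males hypoxia and glycolysis genes -0.93, interferon response genes -0.56, oxidative stress and glutathione genes -0.88, unfolded protein response and heat shock genes -1.01, cell cycle genes -0.68, oxidative phosphorylation genes -1.10, ribosomal protein genes -1.19, steroid hormone and cholesterol synthesis genes -0.67, and for female minus male oxidative phosphorylation genes 0.35. With centring on the tested genes they were, in females, hypoxia and glycolysis genes -0.13, interferon response genes 0.00884, unfolded protein response and heat shock genes -0.25, cell cycle genes -0.0377, steroid hormone and cholesterol synthesis genes 0.0158, in males hypoxia and glycolysis genes -0.24, interferon response genes 0.12, oxidative stress and glutathione genes -0.20, unfolded protein response and heat shock genes -0.33, cell cycle genes 0.00707, oxidative phosphorylation genes -0.41, ribosomal protein genes -0.50, steroid hormone and cholesterol synthesis genes 0.0139, and for female minus male DNA methylation and chromatin regulators 0.0301, oxidative phosphorylation genes 0.0274. Camera tests a list against the other genes, so a list can reverse with its mean on the same side of 0.

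Signal over background limits ratios of dim genes. Of the probes, 53.8% to 60.6% lay above background in APA and 60.3% to 68.7% in control pools, and a bound is given only where a group lay well above background on none of its arrays. Pnp2 in control and Zfp874a in APA female pools did so on 1 of 3 arrays, and their ratios are given as measured although 1 side was near background. Dye-specific correction, other background methods, probe sequence alignment and a model of shared dams were not run.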

Other observations

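The tests of genes named here were chosen only after the results were seen, and none of these values is part of a comparison that passed unless that is said.

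Over the 12 pools, the first principal component held 31.6% and the second 30.1% of the variance. The second separated male from female pools, which also lay on different slides, with values of 5.84 to 29.9 in male and -26.8 to -11.6 in female pools. The first set apart the control pool of male replicate 2 at 61.8, with the other 11 pools between -20.2 and 14.1. Log2 ratios of 2 arrays correlated at 0.0812 (female replicate 3 and male replicate 3) to 0.684 (female replicate 3 and male replicate 2), the highest pair being of different sex and slide. Yolk sac and visceral endoderm genes had array means of -0.381, -0.107 and 0.598 in females.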
